A study of Mus musculus with 64 samples.

How the data were processed

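Transcript levels were measured in whole hearts of male mice on the C57Bl/6J background, kept under 12 h of light and 12 h of darkness, with Illumina MouseRef-8 v2 bead arrays. Total RNA was reverse transcribed with an oligo(dT) primer and amplified as biotin-labelled cRNA, per the labels. The labels assign 64 arrays to 16 groups, made of 2 genotypes (wild type littermates and mice with a cardiomyocyte-specific deletion of BMAL1, called knockout from here on) and 8 zeitgeber times (ZT, hours after lights on) 3 h apart, with 4 arrays each. Each array carries a sample number, used here as its replicate number. Hearts of ZT 0, 6, 12 and 18 carry the numbers 1 to 154 and hearts of ZT 3, 9, 15 and 21 the numbers 156 to 209, so the time points fall into 2 sets of 32 arrays each. The labels number the samples but do not state that each came from a separate mouse, so p-values measure the spread between these samples, part of which may be technical.

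The deposited values, per the file headers, are an average bead intensity per probe and array, with no normalization or background subtraction visible in them. A detection p-value per probe and array, which compares the probe with the negative controls of that array, is deposited beside each intensity, per the file headers. The software that produced both is not given in the sources used here. The authors also deposited a processed intensity for each probe. Set against the scanner intensity of the same array it had a Spearman correlation of 1, and each of the 64 columns matched its own array best. These processed values are linear, 26.2% of them lie below 0, the column medians range from 14.40 to 14.58, and the sorted columns differ by at most 1.95 intensity units, which is what background subtraction and quantile normalization give. That reading comes from the values alone. They were used as an alternative, after values below 0 were set to 0, 16 was added and log2 was taken.

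The background of each scanner column was removed with the normexp model, whose parameters were estimated from the detection p-values, with an offset of 16. The arrays were then quantile normalized and log2 transformed. Of 25697 probes, 12101 had a detection p under 0.01 on at least 4 arrays and were kept. Probes were named from the platform annotation: 23978 had 1 gene symbol, 0 had several and 1719 had none. A gene table from RefSeq matched 23962 of them, and 0 symbols changed. That table was used for names only, and no coordinates are given. One probe per gene was kept, that with the highest mean over all arrays, and unnamed probes were kept as they were, which left 9137 features (8449 named genes and 688 unnamed probes, all called genes in counts below). Of the genes named in the text, 47 had more than 1 tested probe, and in 0 of them did probes past the threshold differ in direction. Another probe missed the threshold for 14 of 42 such genes called in the 24 h mean, 2 of 19 rhythmic in wild type, 5 of 7 rhythmic in knockout and 5 of 7 with a changed rhythm.

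The study design names cosinor analysis and a comparison of its parameters between genotypes, and the fit followed it. Each gene was fitted with limma by a mean, a cosine and a sine term of a 24 h period for each genotype, plus a term for the time set, over all 64 arrays with one shared estimate of the spread. Tests covered the difference of the 2 means (the 24 h mean, knockout minus wild type), the rhythm in each genotype (an F test of cosine and sine), and the difference of rhythm (an F test of both differences). Amplitude is the height of the fitted curve over its mean in log2 units, and the peak is its highest time. P-values were adjusted by Benjamini-Hochberg over the 9137 genes, with a threshold of 0.05. Arntl was also compared at each time in a model with a mean per group.

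Gene lists (32, with 775 entries) were fixed for the clock, metabolism, contraction, ion channels, growth, matrix, stress and signalling, and for markers of other cell types. A shift of each list in the 24 h mean was tested with camera in limma at a preset correlation of 0.01, and also with an estimated correlation and with fry. The fry test asks whether the members move, on balance, one way, and does not compare them with other genes. Enrichment of each list in rhythmic genes was tested with two-sided Fisher's exact tests against all other tested genes. Adjustment was over the lists. Genes of one list are not independent replicates.

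Genes were named by a rule: Arntl and every measured member of the core clock and clock output lists; the 12 largest rises and the 12 largest falls of the 24 h mean past the threshold with the same sign at 8 of 8 times; the 12 largest amplitudes in each genotype; the 12 largest losses and 12 largest gains of amplitude among genes whose rhythm differed; and up to 4 members with the smallest adjusted p in each list. Any gene named outside it is said to have been chosen after its values were seen. The design, the lists, this rule and a set of alternatives were fixed before the data were examined. The alternatives were other background, scaling, filter and probe choices, the deposited processed values, no time set term, each time set alone, an added 12 h harmonic, time as 8 levels, each genotype alone, a trended robust prior, array weights, a threshold of 0.01, and leaving out each array. Blocks of 8 arrays in number order and the removal of 3 arrays of wide spread were added after seeing the data.

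The fit was tested on simulated data, in 5 simulations with the 9137 genes and 100 changed genes of each size and kind of change. A 24 h mean difference of 0.2 was recovered in 52% of genes and one of 0.5 in 98.6%. A rhythm of amplitude 0.25 was recovered in 63.2% of genes in wild type and 57.2% in knockout, and one of 0.5 in 98.3% and 98.2%. The wild type shares pool genes rhythmic in both genotypes and in wild type alone, so they rest on more genes. A difference of rhythm of 0.25 was recovered in 25% of genes and one of 0.5 in 85%. The false share among calls was 5.5% for the 24 h mean, 4.67% and 5.25% for the rhythms in wild type and knockout, and 6.09% for the difference. The simulated noise was independent between genes and between arrays, without the correlation seen between real arrays. These shares are thus not error rates of the real calls. Computation used R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8), and matplotlib 3.10.9 for figures. The number of arrays limits the precision.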

Results

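Whole-heart transcript levels were compared between mice lacking BMAL1 in cardiomyocytes (knockout) and wild type littermates over a day, to find which genes differ in their mean level and in their daily rhythm. BMAL1, encoded by Arntl, is the partner of CLOCK in the transcription factor that drives the circadian clock. There were 8 times of day and 4 arrays per genotype and time, 64 arrays in all. Between 9237 and 10605 of the 25697 probes were detected per array, 9953 ± 318 in wild type and 9972 ± 350 in knockout (mean ± SD, n = 32 each). The median raw signal lay between 119 and 196 intensity units, at 152 ± 16.5 in wild type and 162 ± 19.5 in knockout (mean ± SD, n = 32 each). The number of arrays limits the precision of what follows. Of the 64 arrays, 3 spread more than 1.5 times as widely around their group mean as the median array: knockout ZT9 replicate 170 (2.02 times), knockout ZT9 replicate 206 (1.80 times) and wild type ZT6 replicate 1 (1.64 times).

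The targeted gene itself was not lower in the mean of its log2 values over the day. The 24 h mean of Arntl was 6.64 in wild type and 6.71 in knockout on the log2 scale, a difference of 0.07 ± 0.08 (SE, 32 arrays per genotype, adjusted p = 0.523). Arntl was detected on 23 of 32 wild type and 30 of 32 knockout arrays, so its wild type trough lies near background. A linear mean of Arntl, in which the peak weighs more, was not compared. Its daily rhythm was flattened: the amplitude was 1.60 ± 0.08 in wild type with a peak at ZT 0.90, and 0.59 ± 0.08 in knockout with a peak at ZT 0.17 (SE). The difference in amplitude, knockout minus wild type, was -1.02 ± 0.11 (adjusted p = 2.0e-09 for the rhythm difference). In knockout the Arntl signal was lower near the wild type peak, at ZT 0 (-0.82 ± 0.20, SE, n = 4 per group, adjusted p = 0.0035) and ZT 3 (-0.78, adjusted p = 0.0081). It was higher near the wild type trough, at ZT 12 (0.80, adjusted p = 0.0045) and ZT 15 (1.37, adjusted p = 6.8e-07). The differences at ZT 6 (-0.31, adjusted p = 0.498), ZT 9 (0.51, adjusted p = 0.0843), ZT 18 (0.31, adjusted p = 0.469) and ZT 21 (-0.54, adjusted p = 0.112) did not pass. Where the Arntl probe lies relative to the deleted part of the gene was not determined, so its signal does not check the deletion.

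**Figure D1:**
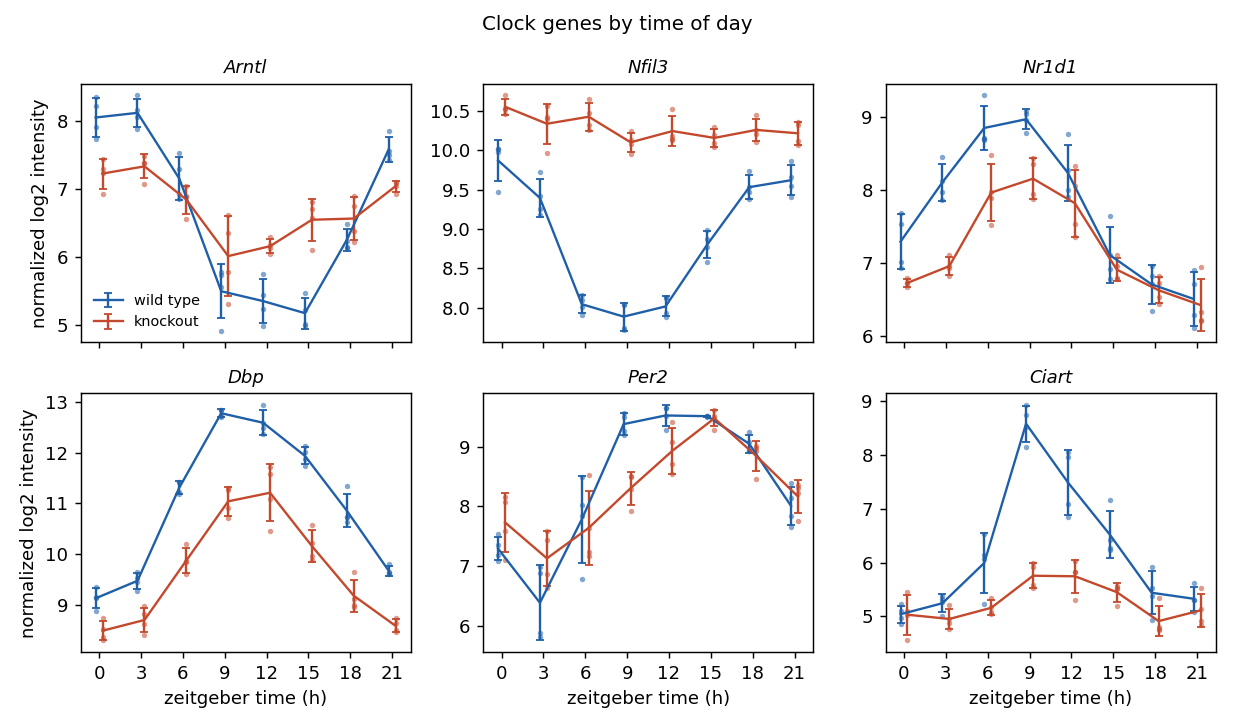
Normalized log2 intensity of 6 clock genes against zeitgeber time (h) in wild type (blue) and knockout (red) hearts; points are single arrays, lines join group means and bars are SD (n = 4). Arntl ran from 8.11 at ZT 3 to 5.18 at ZT 15 in wild type and from 7.33 at ZT 3 to 6.01 at ZT 9 in knockout, and Nfil3 stayed between 10.10 and 10.55 in knockout.

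Among genes that differed with the same sign at 8 of 8 times, Ces1d, Bdh1 and Cdkn1a had some of the largest differences of the 24 h mean. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 7.28-fold (log2 2.86 ± 0.08, SE, 32 arrays per genotype, adjusted p = 3.5e-40). Ces1d, a carboxylesterase, was 23.4-fold lower (log2 -4.55 ± 0.06, adjusted p = 3.8e-59), and Bdh1, the mitochondrial enzyme that oxidizes beta-hydroxybutyrate, was 7.52-fold lower (log2 -2.91 ± 0.13, adjusted p = 3.9e-29). Fhit, a hydrolase of diadenosine triphosphate, rose 7.74-fold (log2 2.95 ± 0.12) and was detected on 3 of 32 wild type and 31 of 32 knockout arrays, so its wild type level lies near background and the size is uncertain. Slc17a7, a vesicular glutamate transporter, rose 6.56-fold and Slc41a3, of a family of magnesium transporters, 4.64-fold. Smaller rises were those of Sprr1a (3.55-fold, detected on 6 of 32 wild type arrays, so of uncertain size), Lrp11 (3.20-fold), the phosphofructokinase Pfkp (3.15-fold) and the pacemaker channel Hcn2 (2.96-fold). Rises were also seen for the potassium channel subunit Kcne1 (2.92-fold), the heat shock protein gene Hspa1l (2.88-fold), the ectonucleotidase Nt5e (2.78-fold) and the mTOR inhibitor Ddit4 (2.63-fold). Falls followed for the prostaglandin D synthase Ptgds (4.83-fold lower), Nampt, the rate-limiting enzyme of NAD salvage (4.04-fold lower) and Ano10 (3.88-fold lower). The clock repressor Nr1d2 was 3.76-fold lower. Also lower were 2210407C18Rik (3.55-fold, but detected on 2 of 32 knockout arrays, so of uncertain size), the potassium channel subunit Kcnv2 (3.17-fold lower) and Mid1ip1 (2.87-fold lower). Further falls were those of Dgat2, an enzyme of the last step of triglyceride synthesis (2.87-fold lower), Tbc1d10c (2.71-fold lower) and the muscle fructose bisphosphatase Fbp2 (2.70-fold lower). All 24 of these genes differed with the same sign at 8 of 8 times.

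In all, 3335 of 9137 genes (36.5%) differed in the 24 h mean, 1535 higher and 1800 lower in knockout. Most differences were small, with a median size of 0.23 among the calls. Past 2-fold were 43 higher and 32 lower genes, and past 1.5-fold 137 and 154. The sign was the same at 8 of 8 times for 882 of the higher and 962 of the lower genes. Unnamed probes made up 103 of the higher and 159 of the lower calls. Of the 3335 calls, 3327 had the same sign at ZT 0, 6, 12 and 18 as at ZT 3, 9, 15 and 21. The calls were made on both sets together, so this agreement is largely built in. In both sets taken alone 1350 passed, and ZT 3, 9, 15 and 21 alone called 1017 higher and 949 lower. Ces1d, Hspa1l, Acot1, Gsta3 and Hbb-b2 belong to families of closely similar genes, so their probes could also read other members and their values are uncertain. Of 42 named genes called here with another tested probe, 14 had one that did not pass: Acot1, Csnk1d, Csnk1e, Cxcl12, Dbt, Fbln1, Gstm1, Hspd1, Irf1, Lamp2, Mylk, Nqo1, Sesn1 and Slc25a20.

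**Figure D2:**
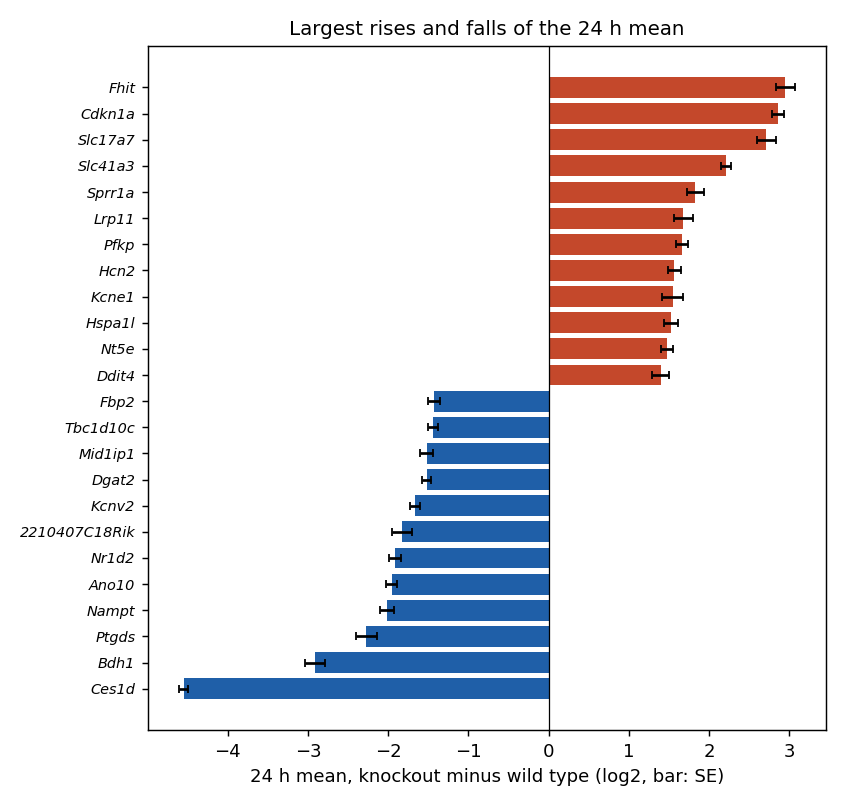
Difference of the 24 h mean, knockout minus wild type (log2), for the 12 largest rises (red) and the 12 largest falls (blue) that kept their sign at 8 of 8 times; error bars are SE. Values run from 2.95 for Fhit to -4.55 for Ces1d.

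Among the clock genes, the repressor Nr1d2 fell by 1.91 ± 0.08 on the log2 scale (SE, adjusted p = 2.6e-31) and its paralog Nr1d1 by 0.52, a value of -0.52 ± 0.07 (adjusted p = 1.8e-08). Ciart (-0.94, detected on 17 of 32 wild type and 7 of 32 knockout arrays, so its size is uncertain), the transcriptional repressor Bhlhe40 (-0.68), Per1 (-0.49), Per3 (-0.44), Rora (-0.32) and the kinase gene Csnk1e (-0.28) were also lower. Clock, which encodes the partner of BMAL1, rose by 0.65 ± 0.05 (adjusted p = 8.0e-17), and Csnk1d (0.33) and Cry2 (0.27) were higher. Per2 did not pass (-0.09 ± 0.11, adjusted p = 0.551). The core clock list held 3 higher and 8 lower genes of 13 measured, with the same counts adjusted over the list alone, and did not pass as a list (adjusted p = 0.0531). It passed by quantile normalization alone (adjusted p = 0.0266), with median scaling (adjusted p = 0.0409), with no time set term (adjusted p = 0.0413) and at ZT 3, 9, 15 and 21 alone (adjusted p = 0.0255). In the clock output list 3 of 13 measured genes were higher and 8 lower, again unchanged when adjusted over the list alone, and the list shifted down (adjusted p = 0.0262, and adjusted p = 0.133 with an estimated correlation). It missed the threshold among genes detected on at least 32 arrays (adjusted p = 0.0617). Its members Dbp (-1.31 ± 0.08), Gpcpd1 (-1.14), Herpud1 (-0.77), Usp2 (-0.72), Tef (-0.66) and Klf15 (-0.40) fell beside Nampt. Klf9 was lower too (-0.22), but its call ended when any of 31 of the 64 arrays was left out. The 24 h mean of Nfil3, a repressor of the same DNA sites that Dbp and Tef activate, rose 2.62-fold (log2 1.39 ± 0.06, adjusted p = 2.6e-31). Leo1 was higher (0.62), as was Cdkn1a, and Klf10 (-0.15) and Tsc22d3 (-0.05) did not pass.

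Lists for the use of branched-chain amino acids, fatty acids and ketone bodies shifted down in knockout, that of fatty acids only at the preset correlation (adjusted p = 0.133 with an estimated correlation). In branched-chain amino acid catabolism 0 of 16 measured genes rose and 11 fell (12 adjusted over the list alone), and the list shifted down (adjusted p = 0.00039, and adjusted p = 0.0165 with an estimated correlation). Bckdhb (-0.72 ± 0.06, SE) and Dbt (-0.66 ± 0.07), subunits of the branched-chain keto acid dehydrogenase, fell most clearly, with Aldh6a1 (-0.41) and Ivd (-0.28). In fatty acid uptake and oxidation 0 of 25 rose and 13 fell (14 adjusted over the list alone), among them Ech1 (-0.43), Decr1 (-0.46), the carnitine-acylcarnitine carrier Slc25a20 (-0.35) and Acot1 (-0.89). The list shifted down (adjusted p = 0.00082, and adjusted p = 0.133 with an estimated correlation). In ketone body metabolism 3 of 4 measured genes fell, also adjusted over the list alone, Oxct1 (-0.42) and Acat1 (-0.23) beside Bdh1, while Bdh2 stood at 0.02. That list shifted down (adjusted p = 0.0041, and adjusted p = 0.0165 with an estimated correlation). Of 19 genes of the tricarboxylic acid cycle 0 rose and 6 fell, also adjusted over the list alone, led by Idh2 (-0.80 ± 0.06) with Dlat (-0.25), Ogdh (-0.27) and Fh1 (-0.13), and the list did not pass (adjusted p = 0.0557), although it did by quantile normalization alone (adjusted p = 0.0486) and with no filter (adjusted p = 0.0039).

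Lists of cardiac growth and of the extracellular matrix shifted up at the preset correlation, and neither did with an estimated correlation (adjusted p = 0.101 and adjusted p = 0.339). In the hypertrophy and fetal program 9 of 19 measured genes rose and 1 fell (10 and 1 adjusted over the list alone), including Rcan1, a calcineurin regulator (1.15 ± 0.06, SE), Ccn2, a matricellular growth factor (1.16 ± 0.07), Ankrd1 (0.73 ± 0.07) and the natriuretic peptide gene Nppb (0.90 ± 0.10). The list shifted up (adjusted p = 0.00082, and adjusted p = 0.101 with an estimated correlation). In extracellular matrix and fibrosis 13 of 41 rose and 3 fell, with the same counts adjusted over the list alone, among them Timp1 (0.79), Col4a2 (0.47) and, in the other direction, Fbln1 (-0.32). That list shifted up (adjusted p = 0.0158, and adjusted p = 0.339 with an estimated correlation), although not at ZT 3, 9, 15 and 21 alone (adjusted p = 0.0541). Ccn2 and Timp1 are in both lists.

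Markers of other cell types moved beside these lists. Of 19 measured myeloid markers 0 rose and 10 fell (12 adjusted over the list alone), for example the antigen-presentation gene H2-Aa (-0.42 ± 0.10, SE), Cd163 (-0.33 ± 0.09), Fcer1g (-0.19) and Laptm5 (-0.17). The list shifted down (adjusted p = 0.0295, and adjusted p = 0.519 with an estimated correlation), but not at ZT 0, 6, 12 and 18 alone (adjusted p = 0.341). Fibroblast markers, of which Col1a1, Col1a2, Dcn and Lum are also matrix genes, held 3 higher and 0 lower of 12 (2 and 0 adjusted over the list alone, adjusted p = 0.482), with Col1a1 at 0.32, Mfap5 at 0.27, Lum at 0.21 and Pdgfra at -0.07. The call of Lum ended when any of 32 of the 64 arrays was left out. Endothelial markers held 0 higher and 5 lower of 17, also adjusted over the list alone (adjusted p = 0.105), led by Icam2 (-0.22), Tek (-0.19), Cdh5 (-0.21) and Emcn (-0.10). That list passed at ZT 3, 9, 15 and 21 alone (adjusted p = 0.0090) and with no filter (adjusted p = 0.0140). Smooth muscle and pericyte markers held 0 higher and 5 lower of 13 (6 lower adjusted over the list alone, adjusted p = 0.105), with Abcc9 (-0.72), Mustn1 (-0.16), Mylk (-0.20) and Vtn (-0.13), and passed with no filter (adjusted p = 0.0424). Skeletal muscle markers held 3 lower of 6 (4 adjusted over the list alone, adjusted p = 0.300), Myl1 (-0.81), Pvalb (detected on 5 wild type arrays and 0 knockout arrays, so no size is given) and Atp2a1 (-0.43, detected on 9 wild type arrays and 1 knockout array), with Mylpf at -0.24. Adipocyte markers held 1 lower of 3 (2 adjusted over the list alone, adjusted p = 0.482), Lipe (-0.22), with Pparg at -0.12 and Adipoq, detected on 9 wild type and 6 knockout arrays, at -0.09. Red blood cell markers held 1 lower of 4 (0 adjusted over the list alone, adjusted p = 0.515), Hbb-b2 (-0.30, a call that ended without any of 19 single arrays), with Alas2 at -0.23, Slc4a1 at -0.22 and Hba-a1 at -0.02. Atrial markers held 1 higher of 10, also adjusted over the list alone (adjusted p = 0.793), the natriuretic peptide gene Nppa (0.67 ± 0.16), with Sln at 0.39, Dkk3 at -0.21 and Kcnj3 at -0.12. The 1 lymphocyte marker measured, Cd52, stood at -0.11 (adjusted p = 0.793 for the list).

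**Figure D3:**
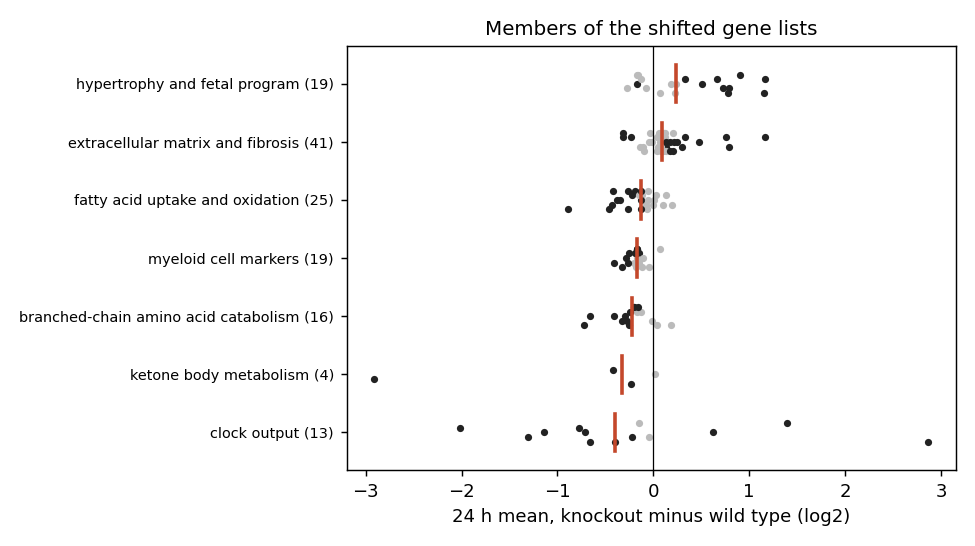
Difference of the 24 h mean, knockout minus wild type (log2), for each measured member of the 7 lists that shifted, with the number of members in parentheses; dark points passed the gene-wise test, grey points did not, and red bars mark list medians. Ketone body metabolism reaches down to Bdh1 at -2.91, and clock output reaches up to Cdkn1a at 2.86.

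The other lists did not pass as lists. Interferon response genes held 0 higher and 10 lower of 20, also adjusted over the list alone (adjusted p = 0.0557), with Psmb9 (-0.30), Gbp2 (-0.30), Ifi27 (-0.24) and Irf1 (-0.24). That list passed with median scaling (adjusted p = 0.0409), with no filter (adjusted p = 0.0089) and at ZT 3, 9, 15 and 21 alone (adjusted p = 0.0251). Triglyceride and lipid storage held 5 higher and 10 lower of 21 (adjusted p = 0.300), with Cidea up (0.81) and Acaca (-0.58), Plin4 (-0.46) and Dgat2 down. Glucose uptake and glycolysis held 6 higher and 9 lower of 20 (adjusted p = 0.947), with Pfkp and Pgam1 (0.51) up and Hk2 (-0.47) and Pdk1 (-0.38) down. Glycogen metabolism held 4 higher and 5 lower of 14 (adjusted p = 0.545), with the phosphorylase Pygl (1.13) and Phkg1 (0.63) up and Ugp2 (-0.30) and Pgm1 (-0.21) down. Oxidative phosphorylation held 6 higher and 12 lower of 44 (13 lower adjusted over the list alone, adjusted p = 0.492), with Atp5o at 0.44, Cox7b at -0.39, Ndufs7 at -0.19 and Atp5c1 at -0.13. Nuclear receptors and mitochondrial regulators held 0 higher and 4 lower of 14 (adjusted p = 0.121): Esrrb (-0.48), Ppargc1a (-0.43), Ppara (-0.20) and Esrra (-0.15). It passed at ZT 3, 9, 15 and 21 alone (adjusted p = 0.0407). The sarcomere list held 8 higher and 4 lower of 21 (adjusted p = 0.375), with Mybpc3 (0.41), Csrp3 (0.28) and Des (0.25) up and Tcap, which encodes the titin cap protein telethonin, 2.43-fold lower. Ion channels and calcium handling held 4 higher and 10 lower of 26 (6 and 11 adjusted over the list alone, adjusted p = 0.998), with Hcn2, Kcne1 and Casq2 (0.41) up and Kcnip2 (-0.84) down. Insulin, PI3K, Akt and mTOR signalling held 5 higher and 9 lower of 30 (adjusted p = 0.515), with Ddit4 up and Pik3r1 (-0.63), Igfbp5 (-0.60) and Sesn1 (-0.48) down. Heat shock and endoplasmic reticulum chaperones held 3 higher and 8 lower of 28 (adjusted p = 0.482), with Hsph1 (0.45) up and Ddit3 (-0.37), Hspd1 (-0.25) and Fkbp4 (-0.22) down. Protein degradation and autophagy held 3 higher and 4 lower of 23 (adjusted p = 0.794), with Lamp1 (0.31) and Sqstm1 (0.29) up and Ulk1 (-0.25) and Lamp2 (-0.15) down. Antioxidant and NAD metabolism held 5 higher and 8 lower of 31 (adjusted p = 0.545), with Nqo1 (0.73) up and Nampt, Gsta4 (-0.44) and Gstm1 (-0.23) down. Glucocorticoid-responsive genes held 2 higher and 9 lower of 17 (adjusted p = 0.545), with Cdkn1a and Ddit4 up and Mt1 (-0.72) and Fkbp5 (-0.50) down. Inflammation and acute phase held 2 higher and 3 lower of 19 (1 and 3 adjusted over the list alone, adjusted p = 0.794), with Cxcl14 at 0.26, Il33 at -0.26, Nfkbia at -0.21 and Cxcl12 at -0.16. Cell cycle genes held 0 higher and 2 lower of 9 (adjusted p = 0.793), Pcna (-0.45) and Mcm5 (-0.21), with Tyms at 0.13 and Ccnd1 at 0.12. Where no count adjusted over the list alone is given here, it equalled the count over all genes.

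Of the 32 lists, 7 shifted at the preset correlation, 2 of them (branched-chain amino acids and ketone bodies) also with an estimated one, and 23 moved one way by fry. The ketone body list has 4 measured genes, with a mean of -0.88 against a median of -0.32. Its estimated correlation was negative (-0.082), below the preset 0.01, so the estimate made no added allowance for correlation in that list. Median, mean and test differed in sign for glucocorticoid-responsive genes (median -0.16, mean 0.07, test down), glucose uptake and glycolysis (median -0.020, mean 0.012, test down), ion channels and calcium handling (median -0.10, mean 0.04, test up) and protein degradation and autophagy (median -0.012, mean 0.0062, test up).

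Wild type hearts kept strong daily rhythms of the clock and its outputs. Dbp, a transcriptional activator of the clock output, had the largest amplitude, 1.86 ± 0.08 (SE, 32 arrays, a 13.1-fold range from trough to peak, adjusted p = 3.0e-28), with a peak at ZT 11.5. Arntl followed at 1.60, then Ciart (1.498, peak ZT 10.7), Per2 (1.49, ZT 13.7), the matrix gene Spon2 (1.41, ZT 1.83), Nr1d1 (1.25, ZT 7.56), Nfil3 (1.05, ZT 21.8), Angptl7 (1.03, ZT 17.5), the metalloprotease Adam19 (0.99, ZT 0.16), Per1 (0.90, ZT 11.4), Slc41a3 (0.87, ZT 3.17) and the glutathione transferase Gsta3 (0.84, ZT 18.1). In all 368 of 9137 genes (4.03%) were rhythmic, with a median amplitude of 0.28, and their peaks were spread over the day. They ranged from 34 genes between ZT 12 and 15 to 62 between ZT 6 and 9. Rhythmic genes were enriched in 5 lists by Fisher's exact test: core clock (10 of 13 genes, also adjusted over the list alone, adjusted p = 4.1e-11), clock output (10 of 13, 11 adjusted over the list alone, adjusted p = 4.1e-11), glucocorticoid-responsive genes (9 of 17, 13 adjusted over the list alone, adjusted p = 4.9e-08), extracellular matrix and fibrosis (11 of 41, 16 adjusted over the list alone, adjusted p = 3.3e-06) and heat shock and endoplasmic reticulum chaperones (5 of 28, also adjusted over the list alone, adjusted p = 0.0302). Time as 8 levels in place of the cosine gave 744 genes. That model has no time set term, so a shift between the time sets also counts there. Array quality weights gave 616 genes, and each time set alone gave 105 (ZT 0, 6, 12 and 18) and 109 (ZT 3, 9, 15 and 21).

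In knockout hearts Dbp still oscillated most, with an amplitude of 1.41 ± 0.08 (SE, 32 arrays, a 7.07-fold range, peak ZT 11.04, adjusted p = 9.1e-22). Spon2 (1.27, peak ZT 2.11), Per2 (1.01, ZT 14.9), Nr1d1 (0.86, ZT 8.75), Nr1d2 (0.83, ZT 11.2), Gsta3 (0.81, ZT 18.4) and Angptl7 (0.79, ZT 18.5) came next, then elastin (Eln, 0.62), the retinal dehydrogenase Aldh1a1 (0.60), the alcohol dehydrogenase Adh1 (0.60), Arntl (0.59) and Inmt (0.56). Another probe missed the knockout rhythm for Nr1d2 (adjusted p = 0.590), Adh1 (adjusted p = 0.0815), Tef (adjusted p = 0.0939), Cdkn1a (adjusted p = 0.0982) and Tsc22d3 (adjusted p = 0.574). In all 126 genes (1.38%) were rhythmic, with a median amplitude of 0.29. Of these 75 were also rhythmic in wild type, against 5.07 by chance if the genotypes were independent (Fisher's exact p = 1.1e-73). That comparison takes genes as independent and does not allow for runs of arrays that hold both genotypes. The peaks of the 75 shared genes lay a median of 0.96 h apart, and 71 were within 3 h. Lists enriched in rhythmic genes were core clock (5 of 13, 9 adjusted over the list alone, adjusted p = 1.7e-05), clock output (4 of 13, also adjusted over the list alone, adjusted p = 0.00036), glucocorticoid-responsive genes (4 of 17, 8 adjusted over the list alone, adjusted p = 0.00076) and extracellular matrix and fibrosis (5 of 41, 10 adjusted over the list alone, adjusted p = 0.0019). The count depended on single arrays and on the model: it was 202 without knockout ZT0 replicate 6, 18 at ZT 0, 6, 12 and 18 alone, 71 with the genotype fitted alone, 61 with blocks of 8 arrays in number order as fixed terms and 1110 with time as 8 levels. More genes were rhythmic in knockout than in wild type at ZT 3, 9, 15 and 21 alone (135 against 109). With time as 8 levels 1110 genes passed in knockout and 744 in wild type. Shifts between the time sets count there too, so these are not counts of rhythms alone.

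The rhythms of Nfil3, Adam19 and Slc41a3 passed in wild type and not in knockout, and differed between genotypes. The p-values below test cosine and sine together, so a change of amplitude, of peak or of both can make them pass. The amplitude of Nfil3 went from 1.05 ± 0.06 to 0.14 ± 0.06 (SE, adjusted p = 1.5e-13), that of Adam19 from 0.99 to 0.17 (adjusted p = 1.5e-10) and that of Slc41a3 from 0.87 to 0.13 (adjusted p = 2.7e-10). All 3 genes had a higher 24 h mean in knockout (Adam19 by 2.49-fold). The fitted amplitude of Ciart, near background at its trough, went from 1.498 to 0.39 (adjusted p = 8.0e-05), the coenzyme Q-binding protein gene Coq10b from 0.73 to 0.14 (adjusted p = 1.1e-07) and Tcap from 0.78 to 0.20 (adjusted p = 0.00011). The same held for the deubiquitinase Usp2 from 0.54 to 0.13 (adjusted p = 0.00023), Leo1 from 0.51 to 0.11 (adjusted p = 0.0078), Ier3 from 0.47 to 0.10 (adjusted p = 0.0162) and Cited4 from 0.46 to 0.05 (adjusted p = 0.0346). Nr1d1 kept a rhythm in knockout with an amplitude of 0.86 against 1.25 (adjusted p = 0.0220 for the joint test, and adjusted p = 0.0106 for amplitude alone over the 75 genes rhythmic in both genotypes). Tef and Cdkn1a stayed rhythmic with an earlier peak by the probe used. The peak of Cdkn1a was at ZT 17.4 in place of ZT 0.99 (adjusted p = 2.4e-07 for the joint test), and its amplitude alone did not pass (0.41 against 0.65, adjusted p = 0.328). The peak of Tef moved by -2.77 h (adjusted p = 0.0256 for the joint test), and its amplitude alone did not pass (0.42 against 0.67, adjusted p = 0.136). Of 7 named genes with a changed rhythm and another tested probe, 5 had one that missed the rhythm difference: Tef (adjusted p = 1.0, with a 24 h mean difference of -1.59), Cdkn1a (adjusted p = 0.0695), Slc41a3 (adjusted p = 0.509), Coq10b (adjusted p = 1.0) and Usp2 (adjusted p = 0.706). Dbp (adjusted p = 0.0519) and Per2 (adjusted p = 0.135) missed the threshold of this joint test.

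In all, the rhythm of 24 genes differed between genotypes, 23 with a lower and 1 (Mapre1, adjusted p = 0.0433) with a higher fitted amplitude in knockout, counted by sign alone. Mapre1, a microtubule plus-end protein gene, differed in peak (ZT 3.91 in wild type, ZT 20.3 in knockout) more than in amplitude (0.10 and 0.12), although its rhythm in wild type alone did not pass (adjusted p = 0.0600). No change of peak is given for Mtf2, rhythmic in neither genotype (adjusted p = 0.0783 and adjusted p = 0.133), or for Gng2, detected on 9 of 32 wild type and 4 of 32 knockout arrays, both chosen after their values were seen. Of the 24 genes, 22 were rhythmic in wild type and 5 in knockout, 19 also differed in the 24 h mean, and 3 were unnamed probes. A further test over the 75 genes rhythmic in both genotypes, not listed in the fixed design, found 4 with a lower amplitude (Arntl, Dbp, Nr1d1 and Per2) and 6 with a shifted peak, 4 earlier and 2 later. The 75 genes were selected on the same arrays, and the adjustment covers them alone. Dbp and Per2 passed only here and missed the joint test over all genes. The shifted genes were Cdkn1a (-7.55 h), Ip6k3 (-4.32 h), Smtnl2 (-3.83 h), Tef (-2.77 h), Nr1d1 (1.20 h) and 1300017J02Rik (5.26 h, detected on 10 wild type and 7 knockout arrays), of which Ip6k3, Smtnl2 and 1300017J02Rik were chosen after their values were seen. Genes with a changed rhythm were enriched in clock output (5 of 13, 7 adjusted over the list alone, Fisher's exact adjusted p = 3.3e-09) and core clock (3 of 13, 7 adjusted over the list alone, adjusted p = 7.2e-05). The 3 core clock genes were Ciart, Nr1d1 and the targeted gene Arntl itself, and the list was not tested without Arntl. Most wild type rhythms that were not called in knockout were not shown to differ: 293 genes were called in wild type only and 51 in knockout only. The calls of Cited4, Tef, Mapre1 and Nr1d1 ended without 20, 9, 35 and 1 of the 64 single arrays, the last being wild type ZT18 replicate 85. Array quality weights gave 38 genes in place of 24. Of the 24, 20 kept their call with runs of 8 arrays as fixed terms and 19 without the 3 arrays of wide spread.

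**Figure D4:**
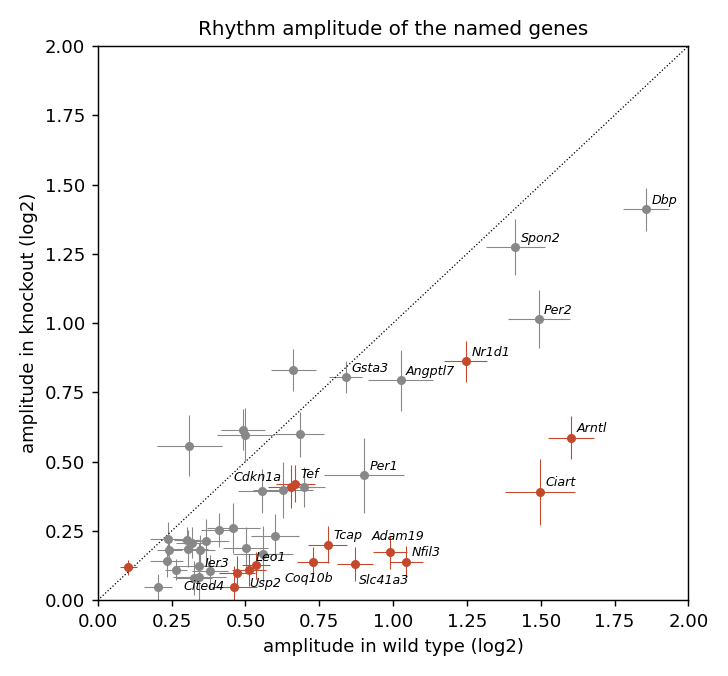
Rhythm amplitude in knockout against wild type (log2) for the 48 named genes rhythmic in either genotype, with SE bars and a dotted line of equal amplitude; red marks the 15 whose rhythm differed. Of the 48 genes, 43 lie below the line. Many were named for a large wild type amplitude or a large loss, so this count does not measure a general loss. Of the 75 genes rhythmic in both genotypes, 44 had a lower and 31 a higher fitted amplitude in knockout.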

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

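The tests of mislabelled arrays, probe position, lost repression, median scaling, cell shares and a common share of clock-keeping cells were chosen after the results were seen, and the label permutations, the persistence of rhythms and the comparison across time sets were chosen before.

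Single arrays stood far from the other 3 of their group in 7 of 96 groups of 6 clock genes, and chance gives about 1 in 20 groups (5%). They were Nfil3 in knockout ZT12 replicate 22 (10.52 against a mean of 10.15 for the others) and wild type ZT0 replicate 70 (9.47 against 10.002), Nr1d1 in wild type ZT6 replicate 1 (9.29 against 8.70) and knockout ZT21 replicate 194 (6.95 against 6.26), Dbp in wild type ZT18 replicate 60 (11.35 against 10.70), and Ciart in knockout ZT18 replicate 140 (5.33 against 4.77) and ZT15 replicate 177 (5.18 against 5.54).

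A difference between the genotypes in the course over the day was tested with an interaction of genotype and 8 times, which 18 genes passed, and with the cosine fit. By the latter 15 named genes differed in rhythm, tested as amplitude and peak together. Their fitted amplitude differences, knockout minus wild type, were those of Ciart (-1.11), Arntl (-1.02), Nfil3 (-0.91), Adam19 (-0.82), Slc41a3 (-0.74), Coq10b (-0.59), Tcap (-0.58), Cited4 (-0.41), Usp2 (-0.41), Leo1 (-0.40), Nr1d1 (-0.38), Ier3 (-0.37), Tef (-0.25) and Cdkn1a (-0.24), and 0.015 for Mapre1. For Tef and Cdkn1a the amplitude alone did not pass (adjusted p = 0.136 and adjusted p = 0.328) and the peak did (adjusted p = 0.0067 and adjusted p = 1.2e-10).

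A random grouping of exchangeable arrays was excluded for the 4 counts by 100 splits each, the real one included. As many genes came from 1 split for the 24 h mean (3335, highest other 1), 1 for the rhythm in wild type (368, highest other 6), 2 for the rhythm in knockout (126, highest other 421) and 1 for the difference of rhythm (24, highest other 1). One split of the knockout times gave 421 genes, over 3 times the real count, which points to a structure of the knockout samples. What made it was not tested. Arrays of the same run of 8 in number order correlate (0.194), and at ZT 3, 9, 15 and 21 the numbers partly follow the time, which the splits do not keep. With runs of 8 arrays as fixed terms 61 genes were rhythmic in knockout, so part of that count could come from the array order.

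The 24 h mean of the Arntl log2 signal was not lower in knockout hearts, with a lower signal at ZT 0 and 3 and a higher one at ZT 12 and 15. A mean of log2 values weighs the wild type trough, near background, as much as the peak. A linear mean, in which the peak weighs more, was not compared, so a lower linear mean in knockout is left open. Arrays with a wrong genotype label were excluded, since 0 of 64 arrays had Ces1d on the side of the other genotype (lowest wild type 12.27, highest knockout 8.47). Wrong labels of time were not tested. A probe outside the deleted part could leave the signal in place (24 h mean difference 0.0690), but the probe sequence was not used, so this stays open. Transcripts of cells that kept the gene could add to it, which was not tested. Lost repression of genes of the same phase stays open too. Of 122 rhythmic genes with a wild type peak from ZT 20 to 4, 49.2% had a higher 24 h mean in knockout, past the threshold or not. Of 118 from ZT 8 to 16 it was 30.5% (Fisher's exact p = 0.0037). As large a gap came from 27 of 100 splits of the genotype labels (highest other 54.1 percentage points, real 18.7). The splits kept the real genotype difference in the values, so a split that by chance resembles the true labels can carry its gap. They thus cannot decide whether the gap exceeds chance. Among called genes, 25 were higher and 9 lower with a peak at ZT 0 to 4, 23 and 11 at ZT 4 to 8, 11 and 32 at ZT 8 to 12, 5 and 30 at ZT 12 to 16, 4 and 37 at ZT 16 to 20, and 16 and 13 at ZT 20 to 24. With phase and difference taken from different time sets the gap gave an exact p of 0.234 in one direction and 5.3e-11 in the other (Fisher's exact test). Shared hearts and a phase effect thus cannot be told apart. The gap was also there with median scaling (Fisher's exact p = 0.0016). Since label splits matched the gap and cannot decide on it, a part of the normalization in it stays open. The deposited values, chosen for this test beforehand, gave 0.0055 but appear to share the quantile step, so they decide nothing.

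The myeloid list shifted down and the matrix list up, calls that both ended with an estimated correlation (adjusted p = 0.519 and adjusted p = 0.339) and in one time set each (myeloid at ZT 0, 6, 12 and 18, adjusted p = 0.341, matrix at ZT 3, 9, 15 and 21, adjusted p = 0.0541). A smaller share of cardiomyocytes would raise the markers of every other cell type alike, but the endothelial score was lower (upper 95% bound -0.0632), although not beyond its spread at ZT 0, 6, 12 and 18 alone (0.0096), where the endothelial list did not pass (adjusted p = 0.665). With expression per cell unchanged, neither that share nor an even fall of all other cells could be the only change. Fibroblast and endothelial scores moved apart (lower 95% bound 0.128, 0.0896 and 0.120 in the time sets alone, and 0.0889 without the 4 markers shared with the matrix list). Without those 4 markers the fibroblast score stood at 0.035 ± 0.028 (SE), so there the gap came mostly from the lower endothelial score. Shares that change by cell type, or a changed expression per cell, were not tested. A smaller share of myeloid cells could account for the myeloid part, with 94.7% of 19 markers lower, but lower expression per cell was not tested. That percentage restates the shift of the list, so it does not decide between them. It is not particular to myeloid cells: 100% of 17 endothelial and 92.3% of 13 smooth muscle and pericyte markers were lower, against 41.7% of 12 fibroblast markers. That a matrix response to the deletion stands behind the higher matrix genes is a hypothesis without a test here.

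Few rhythms were called as changed, although fewer genes were rhythmic in knockout (126 against 368), an order that turned at ZT 3, 9, 15 and 21 alone (135 against 109). The difference test has less power: in the simulations a rhythm of 0.25 in wild type alone was called as a difference in 25% of genes. A wild type rhythm of that size was itself called in 63.2%. The median amplitude of the wild type calls was 0.28, so few calls of a difference do not show that few rhythms changed. With time as an 8-level factor 1110 genes passed in knockout and 744 in wild type, a test that also counts shifts between the time sets. That all of the uncalled wild type rhythms persisted in full with an unchanged peak was excluded. For genes chosen in one time set and measured in the other, the rhythm along the wild type peak was averaged over genes. The ratio of these averages, knockout over wild type, was 0.637 ± 0.060 (SE), with an upper 95% bound of 0.755. An average does not tell how many of these genes weakened or moved their peak, so many could have persisted in full. One common share of cells that keep a clock stays open: the linear amplitude ratios of 20 clock and output genes differed (heterogeneity test over 64 arrays, 0.00031), but such cells could express each gene at their own level, which was not measured. Rhythms driven from outside cardiomyocytes, weakened to a gene-specific degree, could leave this pattern and were not tested.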

How the results depend on the processing

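Blocks of 8 arrays in number order and the removal of 3 arrays of wide spread were chosen after seeing the data, and the other alternatives before. Of the named genes, the 24 h mean kept its direction and its side of the threshold in 2482 cases and missed the threshold in 86 (143 genes), the wild type amplitude in 869 and 49 (46 genes), the knockout amplitude in 360 and 39 (20 genes) and the amplitude difference in 245 and 36 (15 genes), with 3 reversed. The slide is not given, so a slide block was not run. No paired analysis was possible because replicate numbers are not shared between groups. Signal near background limits Fhit, Sprr1a, 2210407C18Rik, Ciart, Per3, Klf15, Ppara, Pvalb, Atp2a1, Pcna, Adipoq, Klf10, Mylpf, Tyms, Gng2, 1300017J02Rik and the Arntl trough.

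At ZT 3, 9, 15 and 21 alone, with fewer arrays, 1017 genes were higher and 949 lower, 109 were rhythmic in wild type and 135 in knockout, and 9 differed in rhythm, 8 with a lower amplitude. At ZT 0, 6, 12 and 18 alone 105 were rhythmic in wild type and 18 in knockout, 9 differed in rhythm, 9 of them with a lower and 0 with a higher amplitude, 6 list tests were rich in rhythms in place of 11, and the Arntl difference was -0.0023 (adjusted p = 0.989). At the stricter adjusted p under 0.01 the counts were 202 rhythmic in wild type, 56 in knockout, and 14 with a different rhythm, 14 lower and 0 higher in amplitude.

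Time as an 8-level factor, with shifts between the time sets counted too, gave 744 genes in wild type and 1110 in knockout. Array quality weights gave 616 rhythmic genes in wild type, and each genotype fitted alone 71 in knockout. Runs of 8 arrays as fixed terms gave 61 in knockout. With weights 38 genes differed in rhythm, 35 lower and 3 higher in amplitude. The 1 gene of higher amplitude became 0 under median scaling, no time set term, the 8-level factor, every probe tested, runs of 8 arrays as fixed terms and without the 3 arrays of wide spread. Lists shifted in the 24 h mean numbered 7, and 11 with no filter, 2 with an estimated correlation and 23 by fry. The Arntl difference, never past the threshold, was -0.057 by quantile normalization without background correction (adjusted p = 0.2002). The difference of Mapre1, amplitude, knockout minus wild type, was -0.024 with weights and -0.016 without the 3 arrays. The cause was not tested for these.

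Leave-one-out, lowest to highest, gave 1509 to 1610 genes higher, 1717 to 1950 lower, 308 to 441 rhythmic in wild type, 106 to 202 in knockout (202 without KO ZT0 replicate 6), 19 to 29 with a different rhythm, 0 to 2 of higher amplitude, 6 to 10 lists shifted, 10 to 14 rich in rhythms, and -0.00504 to 0.026 for Mapre1, amplitude, knockout minus wild type.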

Other observations

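The values on histone genes and on array order below were looked at only after the data were seen, and no explanation of them was tested.

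Core histone cluster genes, a group with no fixed list and no enrichment test, were counted by family. Of 32 measured core histone cluster genes 19 were called higher and 1 lower in the 24 h mean, the latter H2bc18 (log2 -0.60). The H4 genes had a median of 1.20 with 5 of 7 higher, for example H4c18 (1.28 ± 0.08, SE, 32 arrays per genotype), H4c8 (1.23 ± 0.06) and H4c11 (1.18 ± 0.05). The H2B genes had 8 of 9 higher, such as H2bc6 (0.88 ± 0.08), the H3 genes 4 of 6, such as H3c6 (0.71 ± 0.07), and the H2A genes 2 of 10, with a median of -0.14. H4c4 (-0.11) and H4c6 (0.20) did not pass. The counts were the same by quantile normalization alone, by median scaling and in the deposited processed values. These genes were chosen after their values were seen, and they are near-identical copies, so a probe can read several members. Reverse transcription used an oligo(dT) primer, so transcripts without a poly(A) tail would not be read.

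Arrays of the same run of 8 in number order resembled each other beyond their group. Within such runs, counted from the first array, the residual correlation exceeded that of arrays equally far apart in number across runs by 0.098. Runs shifted by 4 arrays gave -0.081, so nearness in number alone does not give this likeness.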
